A study of Rattus norvegicus with 7 samples.

How the data were processed

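The samples were total RNA of rat primary skeletal muscle cells on day 11 of differentiation, 3 untreated and 4 with IL-6 at 1 ng/ml, per the labels. Titles and the series design give the groups; the growth protocol text names IL-6 on the control samples too. RNA was labelled with Cy3 and hybridised to Agilent rat miRNA arrays, 1 array per sample, per the labels' protocols. The deposited scanner files hold spot intensities made with Feature Extraction 10.10.1.1, per the file headers: the processed signal is the background-subtracted intensity of a spot on a linear scale, with no scaling between arrays. The deposited value table equals the total probe signal intensity of the scanner files on all 15095 spots of each array (tolerance 0.001). It is therefore linear, neither centred nor scaled between arrays, and its medians over spots run from -1.35 to 0.10. Probe positions in the files refer to rn4, per the file headers, and no annotation of that build was used here.

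The processed signal was the main value. Control spots and spots marked as outliers, 2.88% to 3.84% of the 14380 others, were left out, and no such spot was saturated. Spots of a probe were averaged, divided by the array's 75th percentile over the 268 probes well above background on all arrays, set to a floor of 15.7 intensity units and put on the log2 scale. A probe counted as well above background where at least a share of 0.5 of its spots did. The floor is the median over arrays of the lowest scaled signal above background. Each miRNA took its brightest probe by the mean over all arrays. A miRNA was tested if Feature Extraction called it detected on every array of at least 1 group, which left 181; 5 of these were at the floor on all arrays. The number of arrays limits the precision: the median SE of a log2 fold change was 0.07.

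The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment over the tested miRNAs and a threshold of 0.05. Lists of related miRNAs were tested with limma's camera at its preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the 11 lists with at least 3 tested members. The lists held 158 entries, of which 154 were matched by name; miR-155-5p, miR-486-5p, miR-148a-3p and miR-378a-3p were not analysed here. They cover muscle-specific miRNAs, miRNAs that rise in myoblast differentiation, satellite cells, inflammation, the miR-17-92, let-7, miR-30, miR-23-27-24, miR-15 and miR-16, miR-181 and Dlk1-Dio3 groups, and markers of fibroblasts and smooth muscle, blood, endothelium, epithelium and nerve.

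miRNAs were named by a rule set before the data were examined: in each direction the 10 largest changes past the threshold without overlap between groups, in each list the members past the threshold up to 4 and then those of highest mean level until 3 were named, and all tested muscle-specific members. Up to 5 bounds per direction were to be named for miRNAs above background in 1 group alone; 19 miRNAs were above background only on IL-6 arrays, and none gave a fold of at least 1. Lists, tests and most alternatives were also set then.

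All 7 arrays shared 1 slide, 1 scan time and 1 scanner voltage, so a slide or scan block did not apply. The controls filled 1 slide row and the IL-6 arrays the other. The alternatives were other scalings (all probes, quantile, none, spike-in), normexp background, the mean of a miRNA's probes, total gene signal, the value table, other floors and filters, limma with trend and robust (for the lists trend alone, as camera has no robust option) or with array weights, blocks for replicate number and slide column, exact permutation tests, and leaving out each array. Chosen after seeing the data were scaling by the median of probe ratios, a filter on probes well above background, leaving out miRNAs at the floor, averaging IL-6 replicates 3 and 4, and leaving out control replicate 3 with IL-6 replicate 1.

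The fit was tested on simulated data with the means and spreads of these arrays for 719 miRNAs, 30 simulations per setting. The spreads were reassigned at random among miRNAs, and noise was drawn independently for each. Deviations that many miRNAs of an array share were not simulated, so the false calls below do not cover them. With none changed there was no false call. With 36 changed, 43.6% of 1.2-fold, 92.2% of 1.5-fold and 99.4% of 2-fold changes were recovered. Under the 75th percentile the median of the unchanged miRNAs shifted by up to 0.26 on the log2 scale with 36 changed and up to 0.11 with none changed. The mean share of false calls was 25.0% with 36 changed and 13.1% with 12 changed, or 40.0% and 40.3% pooled over simulations, with up to 100 false calls in 1 simulation. Scaling by the median of probe ratios gave 4.90% and 4.45%, or 5.11% and 4.71% pooled, with a largest shift of 0.01. The main scaling was kept as set beforehand; in the measured data the median log2 fold change of the tested miRNAs was 0.02 under it and -0.0063 under the median of ratios. Figures were drawn with matplotlib 3.10.9.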

Results

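MicroRNA levels were measured in rat primary skeletal muscle cells, taken from limb muscle of newborn rats, on day 11 of differentiation. Differentiation is induced by moving the cells to a low-serum medium, in which myoblasts leave the cell cycle and fuse. Of the 7 samples, 3 were untreated and 4 had interleukin-6 (IL-6), a cytokine that contracting muscle releases, at 1 ng/ml throughout. Each sample was hybridised to its own 1-colour array with 1730 probes for 719 miRNAs. Between 174 and 185 miRNAs were detected on the control arrays and between 179 and 207 on the IL-6 arrays. Of all miRNAs, 168 were detected on every array and 510 on none. The labels do not say whether the replicates are separate cultures, so p-values measure only the spread between these samples. IL-6 replicates 3 and 4 were the closest pair: the SD of their log2 difference was 0.09, 1.48 times that from spot noise, where the other pairs had 2.16 to 5.16 times.

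The comparison of IL-6 with control asks which miRNAs change when the cytokine is present during differentiation. With IL-6, miR-338-3p rose by 56.3% (log2 fold change 0.64 ± 0.12 SE, 3 control and 4 IL-6 arrays), miR-376a-3p by 37.2% (0.46 ± 0.10) and miR-382-5p by 24.6% (0.32 ± 0.07). The size for miR-338-3p depends on the floor and the background setting. It was 0.17 ± 0.04 with a floor of 2 times the main one, which lies above all 3 control values. It was 0.27 ± 0.14 with normexp background, and it passed in neither (limma). The normexp setting adds an offset of 50 intensity units, which shrinks the fold changes of dim miRNAs. Offset and background method were not tested apart. Both arms of the miR-181a hairpins, whose 5p arm promotes myoblast differentiation, rose: miR-181a-5p by 0.31 ± 0.06 and miR-181a-1-3p by 0.34 ± 0.05 on the log2 scale. In the other direction, miR-129-1-3p fell by 29.5% (log2 fold change -0.50 ± 0.05), and miR-210-3p, which hypoxia induces, fell by 21.2% (-0.34 ± 0.05). With normexp background and its offset, miR-210-3p turned to 0.09. With a floor of 2 times the main one it was at the floor on every array. miR-34c-5p, a target of p53, fell by 17.5% (-0.28 ± 0.04), and miR-132-3p, a target of CREB, fell by 17.1% (-0.27 ± 0.06).

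In all, 9 miRNAs rose and 8 fell among the 181 tested (limma, Benjamini-Hochberg adjusted p from 0.0110 to 0.0447). The other miRNAs that rose were let-7b-5p (0.24 ± 0.04), miR-152-3p (0.19 ± 0.03), miR-196b-5p (0.17 ± 0.03) and miR-185-5p (0.17 ± 0.03). The other miRNAs that fell were miR-6216 (-0.50 ± 0.11), miR-129-2-3p (-0.46 ± 0.07), miR-1949 (-0.26 ± 0.04) and miR-652-3p (-0.16 ± 0.03). The sequences of miR-129-1-3p and miR-129-2-3p are nearly identical, so their probes can share signal and the pair may count as 1 change. No tested miRNA changed by over 2-fold. For each of the 17, every IL-6 array lay beyond every control array, and the exact permutation p was 0.0286, the smallest that 35 splits allow. Of the 181 tested miRNAs, 40 (22.1%) had groups that did not overlap, where chance gives 5.71% for a single miRNA. miRNAs can vary together across arrays, so the excess over that share is not a test of IL-6. With control replicate 3 and IL-6 replicate 1 exchanged, 54 miRNAs had an unadjusted p under 0.05, against 49 with the real groups (limma). The 11 other probes of the 17 miRNAs that were well above background on all arrays had the same direction as the probe used. The second probes of miR-129-1-3p, miR-210-3p and miR-6216 were at the floor on all 7 arrays, those of miR-129-2-3p and miR-382-5p on 5 and 6, and that of miR-338-3p was above background on 5. With the mean of all probes the log2 fold changes were -0.25 for miR-129-1-3p, -0.24 for miR-129-2-3p, -0.25 for miR-6216, -0.17 for miR-210-3p and 0.17 for miR-382-5p.

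**Figure D1:**
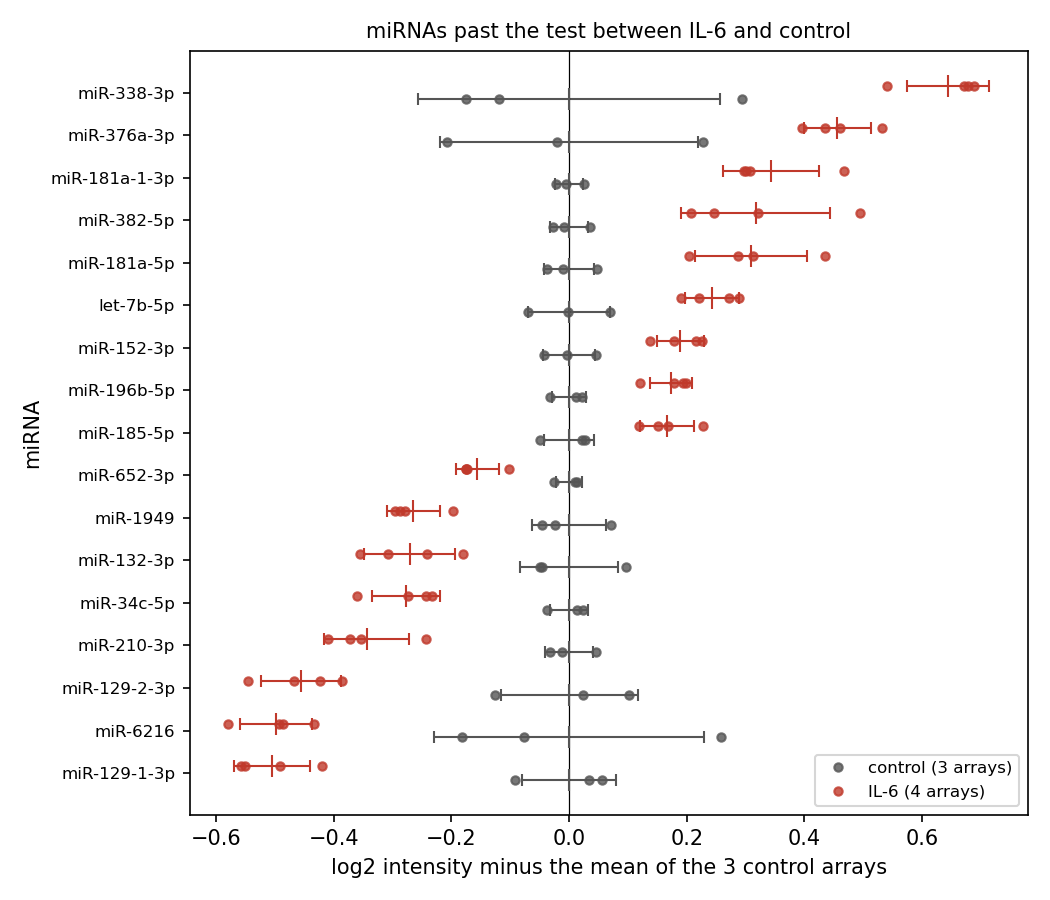
Each point is 1 array, as log2 intensity minus the mean of the 3 control arrays, for the 17 miRNAs that passed the test. Vertical ticks are group means and bars are 1 SD; the 4 IL-6 arrays lie on 1 side of the 3 control arrays for every miRNA, from miR-338-3p (mean 0.64) to miR-129-1-3p (mean -0.50).

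The counts of 9 and 8 became 0 and 0 without control replicate 1 or without IL-6 replicate 3, 0 and 2 without control replicate 2, and 2 and 6 without IL-6 replicate 4 (limma, 31 to 55 miRNAs with an unadjusted p under 0.05 across the 7 such fits). With slide column as a block, limma gave no call in either direction and 52 miRNAs with an unadjusted p under 0.05. This block leaves fewer degrees of freedom for the error. IL-6 replicate 2, alone in its column, adds nothing to the comparison there. The fold changes correlated at 0.986 with the main ones, so the lost calls do not by themselves show a column effect. The deviations of control and IL-6 arrays from their group means correlated across miRNAs at 0.52, 0.19 and 0.13 in the same slide column, and at -0.44 to 0.29 in different columns. With IL-6 replicates 3 and 4 averaged, chosen after seeing the data, 1 miRNA was higher and 5 lower. Data were also simulated with 36 changed miRNAs and independent noise for each miRNA. There the scaling by the 75th percentile gave a mean share of false calls of 25.0% (40.0% pooled over simulations). Scaling by the median of the probe ratios gave 4.90% (5.11% pooled). In the measured data that median-ratio scaling, chosen after seeing the data, gave 11 higher and 14 lower miRNAs, among them 16 of the 17. miR-382-5p no longer passed. Quantile normalization gave 7 higher and 11 lower (38.9% higher, against 52.9%), among them all 8 of the lower miRNAs and 4 of the 9 higher; miR-181a-5p, miR-181a-1-3p, let-7b-5p, miR-196b-5p and miR-382-5p no longer passed. Spike-in scaling gave 4 higher and 0 lower, where the median log2 fold change of all tested miRNAs was 0.18 rather than 0.02. Under spike-in scaling 2 of the 17 passed, and the log2 fold change of miR-652-3p turned to 0.03. All control arrays were in 1 row of the slide and all IL-6 arrays in the other, so slide row and treatment cannot be told apart.

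The imprinted Dlk1-Dio3 cluster, a large group of miRNAs expressed from the maternal chromosome, rose as a list at camera's preset correlation and not with an estimated one (limma camera, Benjamini-Hochberg adjusted p = 0.0161 and adjusted p = 0.456). Of its 30 tested members, 23 had a positive fold change, 2 rose (miR-376a-3p and miR-382-5p) and none fell. Adjusted over the list alone, 0 passed. Of the 23, miR-379-3p, miR-380-3p and miR-381-3p were tested only because all IL-6 arrays detected them. In these and miR-433-3p all controls were at the floor, so a negative fold change was not possible. The mean log2 fold change of the members was 0.11, and between 0.0074 with the 75th percentile over all probes and 0.34 with total gene signal. In these 2 settings the median of all tested miRNAs was -0.12 and 0.04. With the 75th percentile over all probes the list passed (limma camera at the preset correlation, Benjamini-Hochberg adjusted p = 0.00476). Among members detected on all 7 arrays the mean was 0.125 (limma camera at the preset correlation, Benjamini-Hochberg adjusted p = 0.0132). The mean of the 151 other tested miRNAs was 0.0013. The list did not pass limma's fry test for a shift in 1 direction (Benjamini-Hochberg adjusted p = 0.0599). miR-494-3p had a log2 fold change of -0.09 ± 0.14. Without control replicate 3 the list no longer passed (limma camera, Benjamini-Hochberg adjusted p = 0.0749, mean 0.13; range over 29 alternatives 0.000493 to 0.198). It was also lost with no scaling (0.0680), spike-in scaling (0.0787), no filter (0.198) and without both control replicate 3 and IL-6 replicate 1 (0.172), as adjusted p of limma camera.

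The list of inflammation and cytokine-response miRNAs fell as a list, with a mean log2 fold change of -0.14 over 6 tested members (limma camera, Benjamini-Hochberg adjusted p = 0.0200, and adjusted p = 0.456 with an estimated correlation). In limma's fry test for 1 direction it did not pass either (Benjamini-Hochberg adjusted p = 0.0599). Of the 6 members, 5 had a negative fold change and 1 fell, miR-132-3p. Adjusted over the list alone, 2 were lower, miR-132-3p and miR-212-3p, which are from the same locus. miR-221-3p and miR-222-3p also lie within 10 kb of each other, and miR-21-5p and miR-21-3p are arms of 1 hairpin. The members are therefore not 6 separate changes. Their estimated correlation was 0.13, against the preset 0.01. miR-21-5p, which STAT3 induces downstream of IL-6, had a log2 fold change of 0.04 ± 0.08, and miR-221-3p one of -0.09 ± 0.04. The mean of this list was 0.03 without scaling, 0.04 under spike-in scaling and 0.04 in the deposited value table, and the list did not pass there (limma camera, Benjamini-Hochberg adjusted p = 0.0680, 0.0852 and 0.0576; range over 29 alternatives 1.27e-06 to 0.0852). It also did not pass with the replicate block (mean -0.16) or without control replicate 3 and IL-6 replicate 1 (mean -0.16), with limma camera and Benjamini-Hochberg adjusted p = 0.0537 and 0.0559. Without scaling, under spike-in scaling and in the value table, the median of all tested miRNAs moved to 0.17, 0.18 and 0.20. It was 0 with the replicate block and 0.03 without control replicate 3 and IL-6 replicate 1. miR-146a-5p, miR-146b-5p and miR-147 were detected on no array.

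The 4 members of the miR-181 family all had positive fold changes, with miR-181a-5p past the test over all miRNAs and 3 higher adjusted over the list alone. miR-181b-5p had a log2 fold change of 0.29 ± 0.07 and miR-181c-5p one of 0.18 ± 0.06. The probes of these and of miR-181a-5p have similar sequences, so they can share signal and the members may not be separate changes. As a list the family did not pass (limma camera, Benjamini-Hochberg adjusted p = 0.0532, and 0.456 with an estimated correlation). At the preset correlation it passed in 15 of 29 alternatives (limma camera, Benjamini-Hochberg adjusted p from 0.00428 to 0.477). The slide column block was among these 15 (0.0340). In the let-7 family, let-7b-5p rose and the other 7 tested members did not pass; let-7a-5p had 0.02 ± 0.07 and let-7f-5p 0.02 ± 0.10.

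Among miRNAs known to rise when myoblasts differentiate, 1 of 10 tested members rose, miR-181a-5p. miR-29a-3p had a log2 fold change of 0.15 ± 0.06 and miR-24-3p one of -0.10 ± 0.03; adjusted over the list alone, 3 members were higher and 1 was lower. The list did not pass as a shift in 1 direction (limma camera, Benjamini-Hochberg adjusted p = 0.266, and 0.632 with an estimated correlation). It passed limma's fry test for change in either direction (Benjamini-Hochberg adjusted p = 0.000462). That test asks whether members change at all, not whether they change more than other miRNAs. Of all 181 tested miRNAs, 49 had an unadjusted p under 0.05 (limma), so passing it does not set a list apart. In the miR-17-92 list, miR-19b-3p (-0.11 ± 0.07), miR-20a-5p (0.02 ± 0.07) and miR-106b-5p (0.01 ± 0.06) did not pass, and neither did any of the other 7 tested members. No member of the miR-30 list passed over all miRNAs (miR-30a-5p 0.15 ± 0.04, miR-30b-5p -0.0039 ± 0.11, miR-30c-5p 0.09 ± 0.09). The same held for the miR-23-27-24 list (miR-23a-3p -0.12 ± 0.06, miR-27a-3p 0.02 ± 0.10) and the miR-15 and miR-16 family list (miR-16-5p 0.07 ± 0.06, miR-322-5p -0.10 ± 0.20, miR-15b-5p 0.24 ± 0.11). These 4 lists did not pass camera. In the fry test for change in either direction the miR-23-27-24 list passed (limma, Benjamini-Hochberg adjusted p = 0.0396), as did the Dlk1-Dio3 list (0.0268) and the inflammation list (0.0126).

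**Figure D2:**
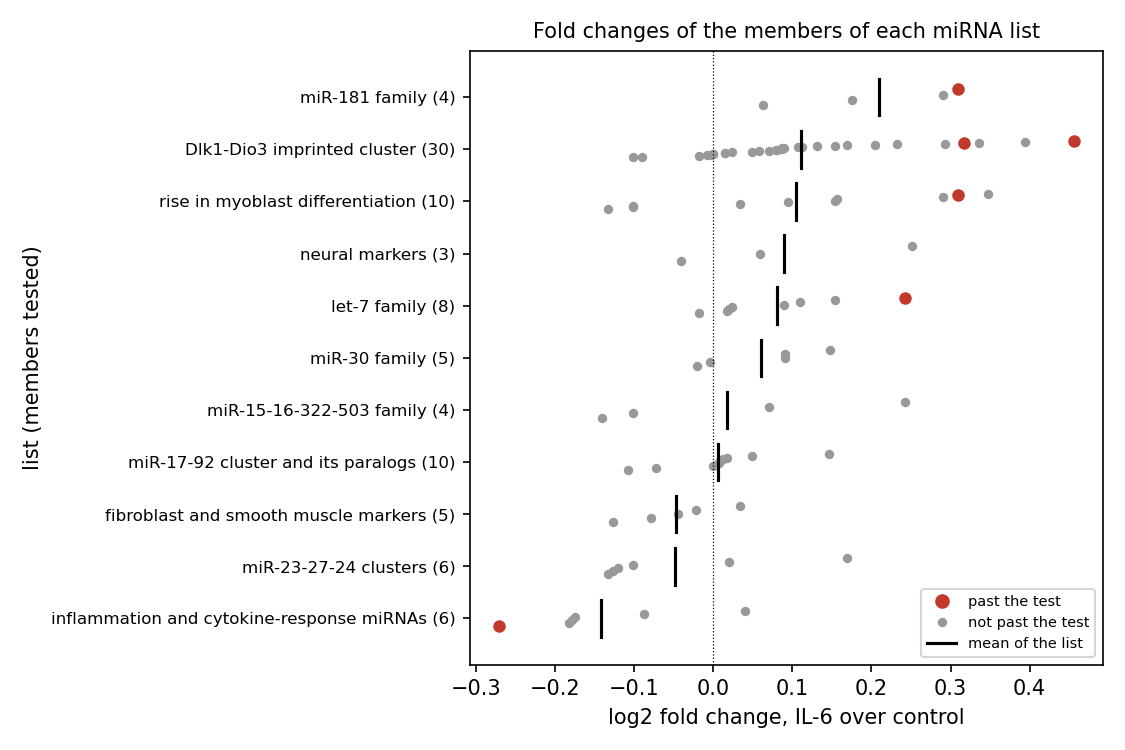
Log2 fold changes, IL-6 over control, of the tested members of each miRNA list with at least 3 of them; points are miRNAs, red ones passed the test, and black ticks are list means. The means run from -0.14 for the inflammation list to 0.21 for the miR-181 family.

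Muscle-specific miRNAs were not detected. miR-1-3p, miR-133a-3p, miR-133b-3p, miR-206-3p, miR-208a-3p, miR-208b-3p and miR-499-5p were below the detection limit on all 7 arrays, control and IL-6 alike. None of their 15 probes was well above background on any array. The highest of the 105 probe signals was 9.23 intensity units, below 12.9, the lowest signal of any probe above background. No fold change is given for them.

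Markers of other cell types were measured in the same way. Of the 6 fibroblast and smooth muscle miRNAs, 5 were detected on every array, at a mean log2 intensity in control of 13.63 ± 0.04 (SD, n = 3) for miR-143-3p, 12.32 ± 0.11 for miR-199a-3p and 11.90 ± 0.11 for miR-199a-5p. Muscle cells also express miR-199a and miR-214 of this list. None of them passed between the groups (log2 fold changes -0.13 ± 0.08, -0.04 ± 0.08 and -0.02 ± 0.06). No endothelial or epithelial marker was detected on any array, and of the haematopoietic list only miR-223-3p was detected, on 1 IL-6 array. Of 8 neural markers, 3 were tested and none passed (miR-218a-5p 0.25 ± 0.12, miR-128-3p -0.04 ± 0.06, miR-219a-5p 0.06 ± 0.09). Of the satellite cell list, miR-31a-5p alone was tested, at -0.15 ± 0.04 (limma, Benjamini-Hochberg adjusted p = 0.0839).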

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

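The tests of array brightness, of slide row, of exchanged arrays, of the muscle-specific miRNAs and of leaving out 1 array for the Dlk1-Dio3 list were chosen after the results were seen. For 51 quantities, the gap between the most distant of the 4 IL-6 arrays and its neighbour was set against the range of the group, and 6 passed Dixon's 95% critical value; chance does so in about 1 in 20. miR-338-3p was 5.04 on IL-6 replicate 2 and 5.17 to 5.19 on the others (log2, ratio 0.887). IL-6 replicate 1 stood apart for miR-181a-1-3p (6.27 against 6.10 to 6.11, ratio 0.938), miR-652-3p (7.26 against 7.19, ratio 0.974) and miR-494-3p (9.16 against 8.66 to 8.72, ratio 0.879). Its mean spike-in signal was 11.69 on the log2 scale, against 11.81 on the others (ratio 0.941). miR-106b-5p was 6.61 on IL-6 replicate 4 and 6.46 to 6.49 on the others (ratio 0.855).

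The 17 miRNAs that passed between IL-6 and control were set against the 35 splits of the 7 arrays, which take no account of slide column: 1 gave 8 or more lower miRNAs, the real one (highest other 5), and 2 gave 9 or more higher miRNAs (highest other 15). Chance is not excluded for the higher count, the lower count or the 17 together. For the lower count the real split stood alone, but 1 of 35 is the smallest share possible, and it was reached for 1 of 3 counts. In fits with fewer arrays or degrees of freedom, 0 were lower: with slide column as a block, without control replicate 1 and without IL-6 replicate 3. The other of the 2 splits with 9 or more higher miRNAs exchanges control replicate 3 with IL-6 replicate 1. It calls 20 miRNAs, none of them among the 17, so an exchange of labels or another structure of the samples stays open. Without both arrays 19 were higher and 10 lower. Array brightness and scaling stay open: under spike-in scaling each of the 17 fold changes moved by 0.186 and 2 of the 17 passed, with miR-338-3p at 0.83 ± 0.16 against 0.64 ± 0.12 and miR-129-1-3p at -0.32 ± 0.11 against -0.50 ± 0.05, while median-ratio scaling kept 16. Slide row cannot be told apart from treatment, because 0 rows held both groups.

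The absence of signal for muscle-specific miRNAs after 11 days of differentiation has no tested biological explanation in the design. The weakest array detected 174 miRNAs, which argues against a general failure of the arrays. That count does not test the sensitivity for these particular miRNAs, which stays open. Few differentiated muscle fibres in the cultures is a candidate explanation with no separate test, since the 14 miRNAs from either arm of these hairpins that were detected on no array include those that prompted it. Probes that do not bind would give the same, and the explanations cannot be told apart, because 0 arrays held a sample known to contain these miRNAs.

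The rise of the Dlk1-Dio3 list was set against probe properties and single arrays. After removing a trend on mean level, probe GC content and probe length, the mean log2 fold change of the members was 0.105 ± 0.0237 (SE over 30 members). Before it was 0.111 ± 0.0251, so these trends accounted for little of the mean. The members were measured on the same 7 arrays and are not replicates. Their SE leaves out the error between arrays and cannot show that the mean differs from 0. The lowest mean without any 1 array was 0.0948, which argues against 1 array as the cause, although the call ended without control replicate 3. Chance stays open for the number of lists: 7 of the 35 splits gave 2 or more lists past the threshold (highest other 4). IL-6 itself stays open too, as does slide row.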

How the results depend on the processing

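The median-ratio scaling, the filter on probes well above background, leaving out miRNAs at the floor, averaging IL-6 replicates 3 and 4, and leaving out control replicate 3 with IL-6 replicate 1 were chosen after seeing the data; the estimated correlation was planned with the tests. Groups that do not overlap nearly fix the direction when an array is left out, and scaling by 1 factor per array moves all miRNAs above the floor alike, so direction says little about stability there: all 17 miRNAs kept it in 24 of 29 refits, the exceptions being no scaling, spike-in scaling, the value table, normexp and a floor of 2 times the main one, where miR-210-3p was at the floor on every array. No call passed in all 29. The main counts were 9 higher, 8 lower and 2 lists. Higher, lower and lists in turn were 0, 0 and 1 with no scaling, 4, 0 and 1 with spike-in scaling, 0, 0 and 5 with normexp background, 0, 0 and 4 with no filter (719 miRNAs tested), and 19, 10 and 0 without control replicate 3 and IL-6 replicate 1. Higher and lower were 0 and 0 with the 75th percentile over all probes, 3 and 2 with total gene signal, 0 and 0 with the series matrix values, 29 and 18 with array weights, 0 and 0 with the slide column block, 11 and 14 with median-ratio scaling, and 1 and 5 with IL-6 replicates 3 and 4 averaged. With a doubled floor 5 were lower, and with an estimated correlation 0 lists passed. The 8 refits with no call had 1 to 52 miRNAs at an unadjusted p under 0.05 (limma). Without 1 array, higher calls ranged from 0 to 9, lower calls from 0 to 7 and lists from 1 to 3. With no scaling, spike-in scaling and the series matrix values in turn, miR-652-3p reversed to 0.0214, 0.0298 and 0.0286, and the inflammation list to 0.0350, 0.0434 and 0.0422; the median of all tested miRNAs there was 0.17, 0.18 and 0.20, and -0.12 with all probes. With normexp background, which includes the offset of 50 intensity units, miR-210-3p reversed to 0.0925. The cause of these differences between settings was not tested, nor was the part of the smaller number of arrays or the larger number of miRNAs tested. With the replicate block, 0 were higher, 3 lower and 1 list passed. That fit leaves out IL-6 replicate 4, which has no control of its number, and has fewer degrees of freedom. The deviations of same-numbered samples correlated at 0.52, -0.18 and 0.26, and those of samples with different numbers at -0.44 to 0.29. The pair at 0.52 also shared a slide column, so these values cannot tell whether the numbers pair the samples. Deviations of arrays in the same slide column correlated at 0.52, 0.19 and 0.13, and pairs in different columns at -0.44 to 0.29. The column block ended all 17 calls, but it leaves fewer degrees of freedom, so that loss does not by itself show a column effect. The exact permutation test of the named miRNAs says nothing about stability, since it was unadjusted and the called ones were named for groups that do not overlap. Of 1595 other values, 1277 kept their side of the threshold, 269 lost it, 42 gained it and 7 reversed; among the 1277, 120 changed sign where neither value passed. A slide or scan block was not run, since all arrays shared both. Signal over background limits dim miRNAs: 510 of 719 were detected on no array.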

Other observations

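The values of 2 miRNAs outside the naming rule were chosen after they were seen, and neither miRNA passed under the main scaling. miR-34b-5p, from the same locus as miR-34c-5p, had a log2 fold change of -0.21, and miR-212-3p, from the same locus as miR-132-3p, one of -0.18.

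The comparison with other splits of the arrays was chosen after the correlation of the arms was seen. The hypothesis that both arms of a hairpin move together was tested on the 22 hairpins with both arms tested. Across hairpins, which are not independent replicates, the fold changes of the 5p and 3p arms had a Spearman correlation of 0.636 (1-sided permutation p = 0.0009, adjusted p = 0.0018 over 2 tests, n = 22 hairpins) and a Pearson correlation of 0.584 (permutation p = 0.0051). Without the 2 hairpins farthest from the median the Pearson correlation was 0.432. Of the 35 splits of the arrays 2 gave a Spearman correlation as high, with a median of 0.321 over all splits, so arms may move together in any difference between arrays and not with IL-6 in particular.

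The hypothesis that miRNAs within 10 kb of each other move together was not borne out at 14 loci. The median absolute difference of log2 fold changes between neighbours was 0.0891, against 0.133 under permutation (1-sided permutation p = 0.11, adjusted p = 0.11 over 2 tests).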
